A study of Drosophila melanogaster with 3 samples.

How the data were processed

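Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos aged 0 to 24 h. The flies carried a transgene that expresses Ken fused to enhanced green fluorescent protein (eGFP), and per the labels the fusion protein was recovered with an antibody against GFP. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The series holds 1 group of 3 biological replicates and no second condition, so the comparisons were made between replicates, between bound places and shifted or flanking places, and between groups of genes.

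Each replicate had a thresholded and a ranked peak list in dm6 coordinates, per the labels and the notes deposited with the files. The aligner, the peak caller, the scaling of signal values between lists and the role of the further source files were not given in the sources used here. The deposited score of a peak runs to 1000 and rises as the irreproducible discovery rate (IDR) falls, and the ranked lists hold the deposited −log10 of that rate. Every peak of the thresholded lists had a score of at least 830, which corresponds to an IDR of at most 0.01. The deposited signal is the peak caller's own value for that peak, and it was used to rank peaks within a list. Ranks from lists of different lengths were set side by side as descriptions only. The summit of a peak was taken from the deposited offset. Of the ranked peaks at an IDR of 0.01 or less, 91, 89 and 95 were absent from the thresholded lists of replicates 1, 2 and 3, and no source used here says why. The thresholded lists over replicates were treated as the authors' pooled lists, and of these only the one named conservative, with 3827 peaks, was used. The ranked lists over replicates were not used here. Read depth is unknown, because the files give no read counts, so the list lengths are reported in its place. Intervals on shares of sites or genes were exact 95% binomial intervals and cover counting error only.

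Peaks of the 3 thresholded lists were merged where they overlapped by at least 1 bp. A merged region holding a peak of every replicate was called a core site, and its centre was the mean of the summits. Analyses of position used the 6 arms X, 2L, 2R, 3L, 3R and 4. The reference genome has the arm lengths of the same assembly, and no peak end exceeded them; on 2R the highest peak end was 25285890 in an arm of 25286936 bp. Transcription start sites (TSSs) were the 19607 starts of the 13945 protein-coding genes in the Ensembl annotation. Of the members of 17 gene lists, 2 symbols of the ecdysone list named 1 gene, so 15 of its 16 entries were tested, and every other entry was matched.

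Overlap between replicates was the percent of one list's peaks that overlapped a peak of the other by at least 50% of the shorter peak. It was tested by a one-sided permutation test with 1000 random circular shifts of one list along each arm, for which 0.001 is the smallest p possible. The percent of core sites within 500 bp of a TSS was tested in the same way. Motifs were searched on both strands within 50 bp of the centre and in a window of equal width centred 500 bp away on a random side. A two-sided exact sign test compared both windows, with Benjamini-Hochberg adjustment over 12 motifs. A gene was called bound when a core site centre lay within 1 kb of one of its TSSs. Lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, adjusted over the 17 lists. The window of 50 kb to each side of ken was compared with 1000 windows of the same width around other genes. Sites are not independent replicates, and correlations of signal are across sites.

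The text names ken, each JAK/STAT gene with a core site in its span or within 1 kb of a TSS, the nearest gene of the 20 core sites with the best mean rank, and up to 4 bound genes of each other list by best mean rank. Groups, lists, motifs, tests and this rule were fixed before the data were examined. Alternatives covered the threshold, the overlap rule, each replicate left out, at least 2 of 3 replicates, the conservative list, the distance to the TSS, the motif window and control sequence, the rule for bound genes and the width at ken. The deposited lists already end at an IDR of 0.01, so the stronger 50% of each list by signal took the place of the stricter threshold that had been planned. An IDR of 0.05 and of 0.001, read from the ranked lists, shuffled sequence for the other motifs, and leaving out each replicate at ken and in the mean number of peaks were chosen after seeing the data.

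Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The calculations were tested on simulated data. Of 3143 simulated peaks, 12.7% were planted in a second list and 13.0% were recovered as overlapping. With 40% of 1384 simulated sites placed at TSSs, 46.5% lay at promoters where 46.9% were planted or fell there by chance. A Ken motif planted in 5% of the 1384 core site windows raised the share to 16.0% where 15.9% had been built in, with an exact sign test p of 0.0100. Of 200 random lists of 40 genes, 1.5% had a Fisher's exact p under 0.05.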

Results

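The data are peak lists from anti-GFP ChIP-seq of whole embryos expressing Ken fused to eGFP. Ken, the product of ken and barbie, is a zinc-finger repressor of the BCL6 family that was described as acting on part of the targets of the JAK/STAT pathway. There was 1 group with 3 biological replicates. The thresholded lists held 3144 peaks in replicate 1, 1856 in replicate 2 and 2256 in replicate 3, a mean of 2418.7 ± 659 (SD, n = 3). Their median widths were 280, 264 and 264 bp, and the full ranked lists held 102849, 101546 and 123371 peaks.

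The first question was whether the replicates placed the fusion protein at the same sites. They did at 1384 core sites, which were found in each of the 3 lists. Another 747 regions were called in 2 replicates and 1514 in 1, and 1046 of the latter were from replicate 1, which had the longest list. Of the peaks of replicate 2, 87.5% overlapped one of replicate 1 and 79.9% one of replicate 3. For replicate 3 the shares were 81.5% in replicate 1 and 65.4% in replicate 2, and for replicate 1 they were 50.9% in replicate 2 and 57.9% in replicate 3. Circularly shifted lists overlapped by 0.370% to 0.656% on average, and each of the 6 comparisons had a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. Across the 1384 core sites, the deposited signals had Spearman correlations of 0.815 between replicates 1 and 2, 0.826 between 1 and 3 and 0.821 between 2 and 3. The count of core sites depends on the rule, with 2131 sites in at least 2 of 3 replicates and 774 when only the stronger 50% of each list was used.

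Most of the strongest core sites lay close to the start of a gene. The site ranked first in all 3 replicates lay on 3L at 19590494 to 19590751 (dm6), in intergenic sequence with its centre 95 bp upstream of CG14100 (FBgn0036889). Its deposited signals were 998.5, 820.2 and 927.9 in replicates 1 to 3. The 51 bp around its centre, 19590594 to 19590644, read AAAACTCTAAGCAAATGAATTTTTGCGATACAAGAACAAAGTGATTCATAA on the plus strand. The sites with ranks 2 and 3 were also the same in every replicate. Rank 2 was held by a site 43 bp upstream of Ugalt, a UDP-galactose transporter gene (X, 2703764 to 2704025), and rank 3 by a site 105 bp upstream of Tcs5 (3L, 5139381 to 5139631), both in intergenic sequence.

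Among the 20 core sites with the best mean rank, 13 lay within 500 bp of a TSS and 16 within 1 kb. Genes of the mitochondrial ribosome were the nearest to a pair of them, mRpL41 (136 bp upstream) and mRpL23 (78 bp downstream). PNPase, a mitochondrial RNA nuclease, had a site 85 bp upstream of its nearest TSS, in sequence annotated as 5′ UTR, and eIF6, a factor of 60S ribosome formation, had one 101 bp upstream. Genes of chromatin and transcription in this set were ph-p, a Polycomb group gene (intron, 503 bp upstream of the nearest TSS), Chro, which encodes Chromator (5′ UTR, 91 bp downstream), the HMG-box gene HmgZ (568 bp upstream), and Adf1, a transcription factor (784 bp downstream). The wing vein gene px (202 bp upstream), CenG1A (108 bp upstream), CG7601 (92 bp upstream), CG5611 (112 bp upstream) and CG1888 (223 bp upstream) also had sites close to a TSS. Farther away were the sites nearest to CG11050 (1030 bp downstream, in an intron), CG32772 (1263 bp downstream, in an intron), tara (3153 bp upstream) and CG13323 (11909 bp downstream of the TSS, in intergenic sequence).

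The second question was where core sites lie relative to genes. They were concentrated at promoters: 755 of 1384, or 54.6% (exact 95% interval 51.9 to 57.2), had their centre within 500 bp of a TSS, against a mean of 11.5% for shifted sites, a 4.75-fold excess. In the separate lists the share was 52.1% ± 1.97 (SD, n = 3). Promoter sites sat upstream of the start, with a median position of 99 bp upstream and quartiles of 164 and 45 bp upstream, and 652 of them, 86.4%, were upstream of the nearest TSS. Outside promoters, coding exons held 4 core sites (0.289%, against 13.9% for shifted sites) and 3′ UTRs held 6 (0.434%, against 4.59%). Introns held 419 sites or 30.3% (39.3% for shifted sites) and intergenic sequence 193 or 14.0% (29.95% for shifted sites). The promoter excess and the deficits in coding exons, 3′ UTRs, introns and intergenic sequence each had a one-sided permutation p of 0.001, the smallest possible, whereas the 5′ UTR share outside promoters (0.506%, against 0.792%) had a permutation p of 0.159 for a deficit. All shares are of the 1384 core sites, so the promoter excess by itself lowers those of the other positions. The tests therefore do not show that sites outside promoters avoid introns or intergenic sequence. Core sites had 0.0208 times the shifted share in coding exons and 0.0945 times in 3′ UTRs, but 0.771 times in introns and 0.466 times in intergenic sequence. The density of core sites was 12.3 per Mb on X, 10.8 on 2L, 10.8 on 2R, 9.57 on 3L and 9.38 on 3R, and arm 4 held 0.

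**Figure D1:**
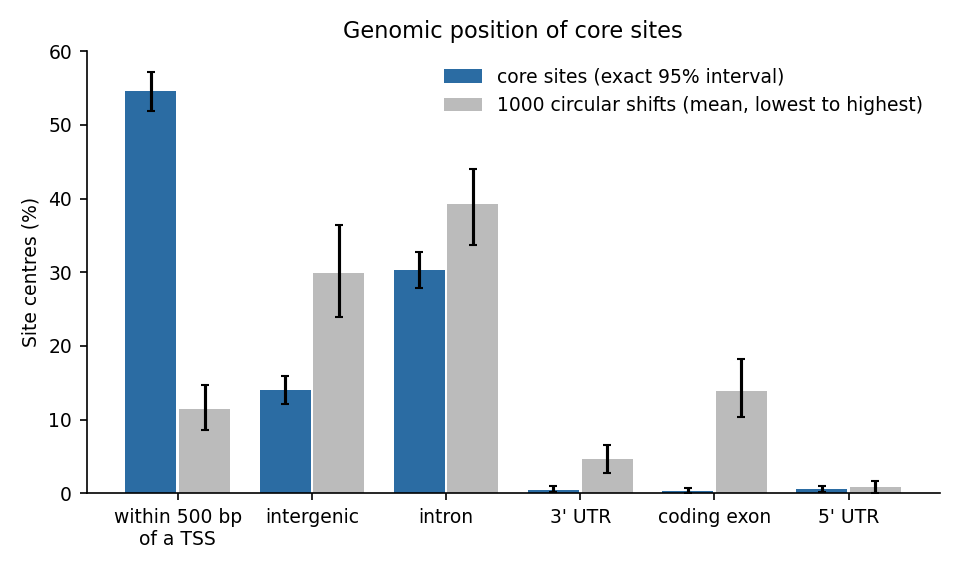
Percent of core site centres (blue, exact 95% intervals) and of circularly shifted sites (grey, mean with the lowest and highest of 1000 shifts) by genomic position; the positions to the right of the first pair leave out sites within 500 bp of a TSS. Core sites reach 54.6% within 500 bp of a TSS, where shifted sites average 11.5%, and are nearly missing from coding exons.

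The third question was whether core sites hold GNGAAAK, the motif described for Ken in vitro. They did not hold it more often than neighbouring sequence: 159 of 1384 sites (11.5%, exact 95% interval 9.86 to 13.3) had a match within 50 bp of the centre, against 13.2% of the flanking windows. The difference was -1.73 percentage points (95% interval -4.15 to 0.684), with an exact sign test p of 0.178 and an adjusted p of 0.267 over 12 motifs. In the separate lists the share was 12.5% ± 0.144 at summits and 12.9% ± 0.742 in flanks (SD, n = 3). Against shuffled copies of the centre windows the difference turned to 1.81 percentage points higher, with an exact sign test p of 0.142. Matches to the STAT site TTCNNNGAA (3.32% against 2.46% in flanks, adjusted p = 0.276 by exact sign test) and to a BCL6-like site (0.939% against 0.578%, adjusted p = 0.46) did not differ detectably either.

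Other motifs did differ. TATCGATA, the element bound by DREF and, in part, by the insulator protein BEAF-32, was found at 25 core sites (1.81%) against 0.145% of flanks (adjusted p = 3.39e-05, exact sign test), and was equally rare in shuffled sequence. TATAAA was found in 22.3% of centres and 10.04% of flanks (adjusted p = 1.65e-16, exact sign test), but shuffled centre windows with the same dinucleotides had it in 21.2% (exact sign test p = 0.459), so there was no detectable excess over shuffled sequence. Motif1 (GGTCACACT) was found at 7 sites and in 0 flanks, with an adjusted p of 0.0426 by exact sign test, which became 0.0938 against shuffled sequence. The GAGA factor site GAGAGAG was rarer at centres than in flanks (0.506% against 2.17%, adjusted p = 0.000764, exact sign test) and so was the Twist E-box CACATG (3.90% against 5.85%, adjusted p = 0.0426). Neither differed from shuffled sequence (adjusted p of 0.845 and 0.826). The Zelda, PHO, CACGTG and poly-A motifs had adjusted p of 1, 0.581, 0.151 and 0.267 by exact sign test. Centre windows were richer in A and T, at 65.5% ± 9.56 against 55.8% ± 10.5 in flanks (SD across 1384 sites), and were the richer window at 1032 sites and the poorer at 333.

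**Figure D2:**
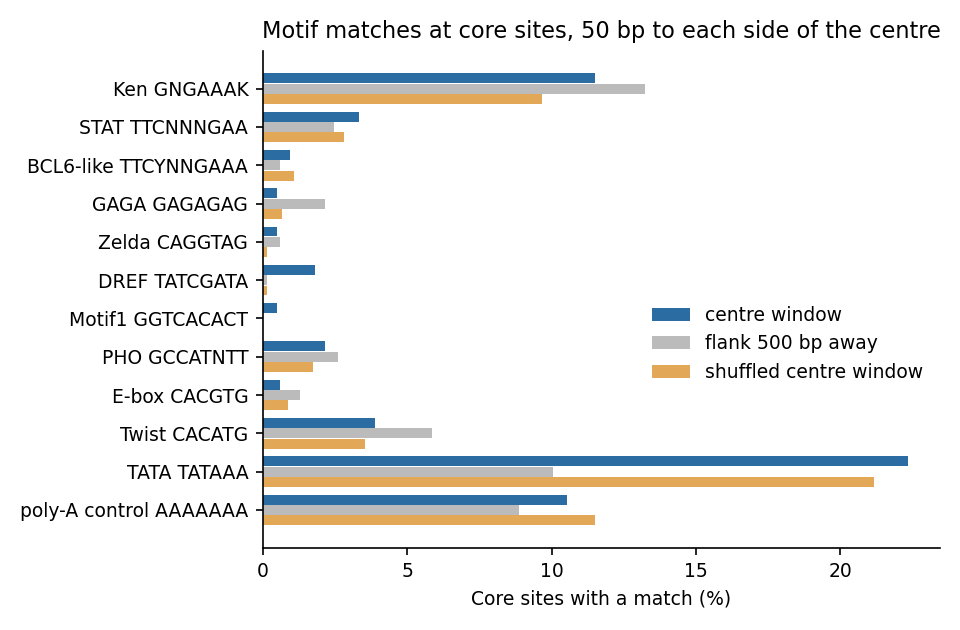
Percent of the 1384 core sites with a match to each of 12 motifs in the window of 50 bp to each side of the centre (blue), in the flanking window (grey) and in the centre window after shuffling that keeps dinucleotide counts (orange). The Ken motif stands at 11.5% at centres and 13.2% in flanks, and TATAAA at 22.3% at centres but 21.2% after shuffling.

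The fourth question was which groups of genes had a core site near their start. In all, 1278 of 13945 protein-coding genes (9.16%) were bound, and 4 of 17 lists passed an adjusted p of 0.05 by Fisher's exact test. Genes of the cytoplasmic ribosome were bound most clearly, 37 of 93 (39.8%, exact 95% interval 29.8 to 50.5), against 8.96% of other genes (odds ratio 6.71, adjusted p = 3.04e-14). The share was 67.7% with the conservative list, 53.8% with at least 2 of 3 replicates and 22.6% with the stronger 50% of each list, and the list passed in each setting. Their best ranked sites were at RpS27 (5 bp upstream, ranks 134, 71 and 83 in replicates 1 to 3), RpL23A (79 bp upstream, ranks 108, 89 and 122), RpL7 (30 bp downstream, ranks 150, 164 and 60) and RpL34b (82 bp upstream, ranks 192, 153 and 81).

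Heat shock genes were bound in 6 of 14 cases (42.9%, exact 95% interval 17.7 to 71.1, adjusted p = 0.00522), through 5 distinct sites. The small heat shock gene Hsp27 had the best of them, 148 bp upstream at ranks 41, 67 and 75, followed by Hsp83 (104 bp upstream), Hsp26 (101 bp upstream) and the constitutive chaperone gene Hsc70-4 (178 bp upstream). With only the stronger 50% of each list, 7.14% of heat shock genes were bound, with an adjusted p of 1 by Fisher's exact test, and at an IDR of 0.001 the share was 21.4% with an adjusted p of 0.268. The Hsp27 and Hsp26 sites lie close together on 3L (centres 9383915 and 9377528). Fisher's exact test and the interval treat neighbouring genes as independent, so both are likely too narrow. With circular shifts, which keep the spacing of sites but use random positions, the adjusted permutation p was 0.0226.

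Polycomb and trithorax group genes, which encode regulators that keep genes silent or active through development, were bound in 6 of 20 cases (30%, exact 95% interval 11.9 to 54.3, adjusted p = 0.0313). The best ranked were ph-p (ranks 8, 10 and 5), brm, the ATPase of the Brahma remodelling complex (132 bp upstream, ranks 69, 77 and 62), E(z), the histone H3 methyltransferase (40 bp downstream), and Su(z)12, its partner (166 bp downstream). ph-p and ph-d, both in the count, are neighbouring copies of one another, so reads at their shared sequence may not be separable. The share stayed at 30% with sites in at least 2 of 3 replicates, where other genes gained sites and the adjusted p was 0.124, and it was 35% with the conservative list, with an adjusted p of 0.26. The list also missed the threshold without replicate 2 (adjusted p = 0.0853, Fisher's exact test), without replicate 3 (0.0541) and at an IDR of 0.05 (0.0858), and passed without replicate 1 (0.0422). It also passed with the stronger 50% of each list (adjusted p = 0.00447, Fisher's exact test), at an IDR of 0.001 (0.0131), with the number of TSSs in a logistic model (0.0474) and with circular shifts (permutation, 0.017). The shifts compare the list with random positions, where sites lose their preference for promoters, and not with other genes. With the gene span and 2 kb to each side the share was 55%, with an adjusted p of 0.00205 in the model with log gene length.

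Odorant and gustatory receptor genes, which are expressed in sensory neurons, were bound less often than other genes, 1 of 119 (0.84%, adjusted p = 0.0026, Fisher's exact test), and the 1 was Or88a. Their adjusted p was 1 when shifted sites replaced Fisher's exact test and 0.129 with the stronger 50% of each list. Shifted sites lie near TSSs less often than core sites, so they leave less room for a deficit than other genes do. Lists of embryonic patterning did not differ detectably from other genes. By Fisher's exact test, the gap and terminal list had 1 of 12 bound (bcd, 148 bp upstream, adjusted p = 1), the tracheal list 1 of 12 (apt, adjusted p = 1), the terminalia list 1 of 16 (Dll, 64 bp upstream, adjusted p = 1), and the pair-rule and segment polarity list 0 of 16 (adjusted p = 0.839), as for 0 of 8 Hox genes (adjusted p = 1). Neurogenesis had 1 of 22 (elav, 263 bp upstream, ranks 151, 100 and 174), mesoderm and muscle 2 of 19 (tin, the heart gene tinman, 185 bp upstream, and sls, 274 bp upstream), signalling 1 of 22 (spi, an EGF receptor ligand, 149 bp upstream) and the germline list 1 of 14 (bgcn, 129 bp downstream), each with an adjusted p of 1 by Fisher's exact test. Ecdysone response genes (0 of 15) and chorion and yolk genes (0 of 16) each had an adjusted p of 0.839 by Fisher's exact test. With the number of TSSs in a logistic model across all genes, the ecdysone list passed at an adjusted p of 0.0474. It passed as a list bound less often by the 1 kb rule, so that 5 lists passed. Counting the gene span and 2 kb to each side, 46.7% of the ecdysone list held a core site, and the list did not pass. By the 1 kb rule the ecdysone share was 20% with the conservative list, where all genes stood at 19.8%. It was 6.67% without replicate 3 and stayed at 0% without replicate 1 or replicate 2. The germline share moved from 7.14% to 28.6% without replicate 2 (adjusted p = 0.221, Fisher's exact test) and to 35.7% with at least 2 of 3 replicates (adjusted p = 0.113). The tracheal share moved to 16.7% without replicate 2 (adjusted p = 0.774, Fisher's exact test) and the signalling share to 9.09% without replicate 3 (adjusted p = 1). With the conservative list they were 41.7% (adjusted p = 0.235, Fisher's exact test) and 31.8% (adjusted p = 0.334), where all genes stood at 19.8%. With 8 to 22 genes in a list, intervals were wide: 0 of 16 still allows a share of up to 20.6% by the exact 95% interval.

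**Figure D3:**
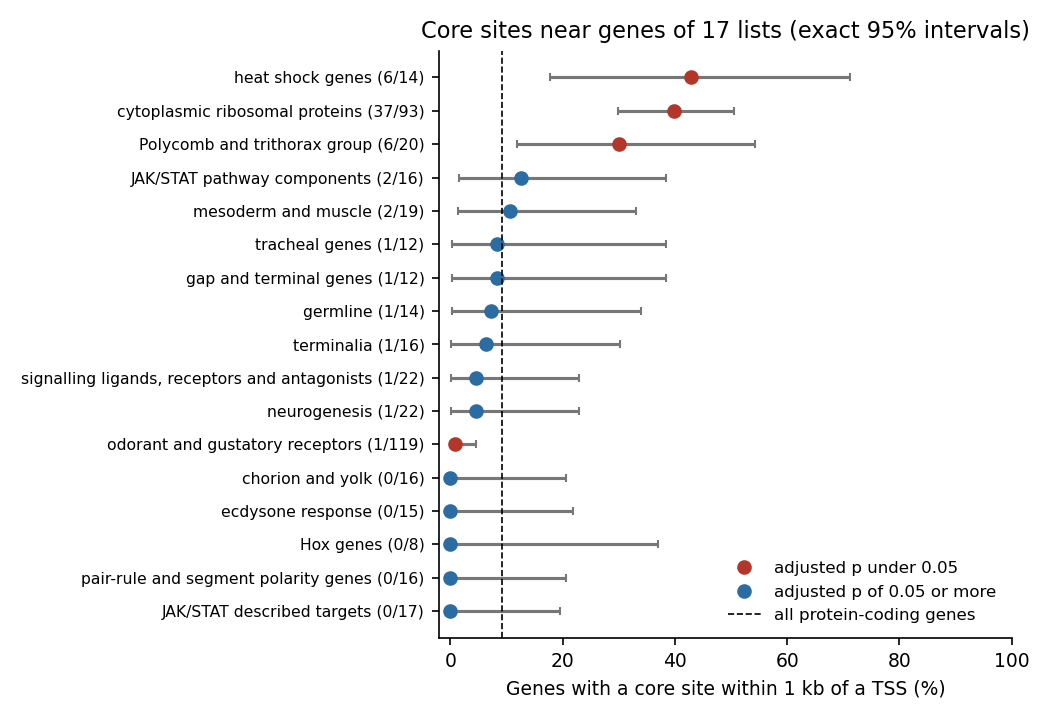
Percent of the genes of each of 17 lists with a core site within 1 kb of a TSS, with exact 95% intervals and the numbers bound and tested in brackets; the dashed line marks the 9.16% of all protein-coding genes. Heat shock, ribosomal protein and Polycomb and trithorax genes (red) lie to the right of the line, and odorant and gustatory receptors (red) to its left.

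The JAK/STAT pathway was the group in which Ken had been described to act, and its genes did not differ detectably from others in how often they were bound. Of 16 pathway components, 2 (12.5%, exact 95% interval 1.55 to 38.4) had a core site within 1 kb of a TSS (adjusted p = 1, Fisher's exact test), and of 17 described targets 0 did (adjusted p = 0.839, exact 95% interval up to 19.5%). Counting sites anywhere in the gene, 5 components and 3 targets had at least 1 core site. The transcription factor gene Stat92E had 1 in an intron, 926 bp from a TSS (3R, 20550036 to 20550320). Its feedback inhibitor Socs36E, which is in both lists, had 1 intronic site 6925 bp downstream of a TSS (2L, 18145318 to 18145642). The phosphatase gene Ptp61F had 2 intronic sites, 18122 and 28464 bp upstream of its nearest TSS, and apt, which encodes a regulator in border cells, had 3, of which 2 were intronic and the nearest to a TSS, 134 bp upstream, lay in a 3′ UTR. Of the targets, zfh1 had an intronic site 1475 bp upstream of the nearest TSS (3R, 30781649 to 30781933, ranks 218, 204 and 420), and RhoGEF64C had one 5461 bp downstream. Core sites outside the gene span are not in these counts, and those more than 1 kb from a TSS were looked up by nearest gene after the values were seen. Of the targets, chinmo had 6 (1057 to 18417 bp from its TSS, mean ranks 557 to 1779), slbo 2 (6349 and 4531 bp, mean ranks 62 and 63.7), and vvl, zfh1 and ems 1 each; of the components, upd1 had 1. With the gene span and 2 kb to each side, 37.5% of components and 29.4% of targets held a site. A logistic model across all genes that also held log gene length gave adjusted p of 0.319 and 0.67 for the lists. By the 1 kb rule the shares moved with the peak list, and no adjusted p fell below 0.05 by Fisher's exact test. With the conservative list 37.5% of components (adjusted p = 0.26, Fisher's exact test) and 23.5% of targets (adjusted p = 0.807) were bound, where all genes stood at 19.8%. With at least 2 of 3 replicates the shares were 18.8% and 5.88%, and at an IDR of 0.001 the share of components was 0%.

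The last question was what the lists show at ken itself (FBgn0011236, 2R, 23870273 to 23877442, plus strand). Of the core sites, 2 lay in introns of the gene. The stronger (23873514 to 23873848) was centred 3401 bp downstream of the TSS, with ranks 473, 356 and 721 in replicates 1 to 3. The other (23871414 to 23871773) was centred 1309 bp downstream, with ranks 1685, 1113 and 1579. At the start of the gene, replicate 1 had a peak with its summit at 23870322 and replicate 3 one at 23870260, and replicate 2 had none in its thresholded list. Within 50 kb to each side there were 5 core sites, against 1.56 ± 1.504 (SD) in 1000 windows around other genes, of which 42 held as many or more, a share of 0.042. The windows were not matched for gene density, and most core sites lie at promoters. The share therefore does not separate an excess at ken from that of a gene-dense region. The strongest of the 5 was the eIF6 site (ranks 14, 6 and 14), and the others outside ken lay at Snap29 and bgcn. Without replicate 3, windows with as many sites made up a share of 0.07.

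**Figure D4:**
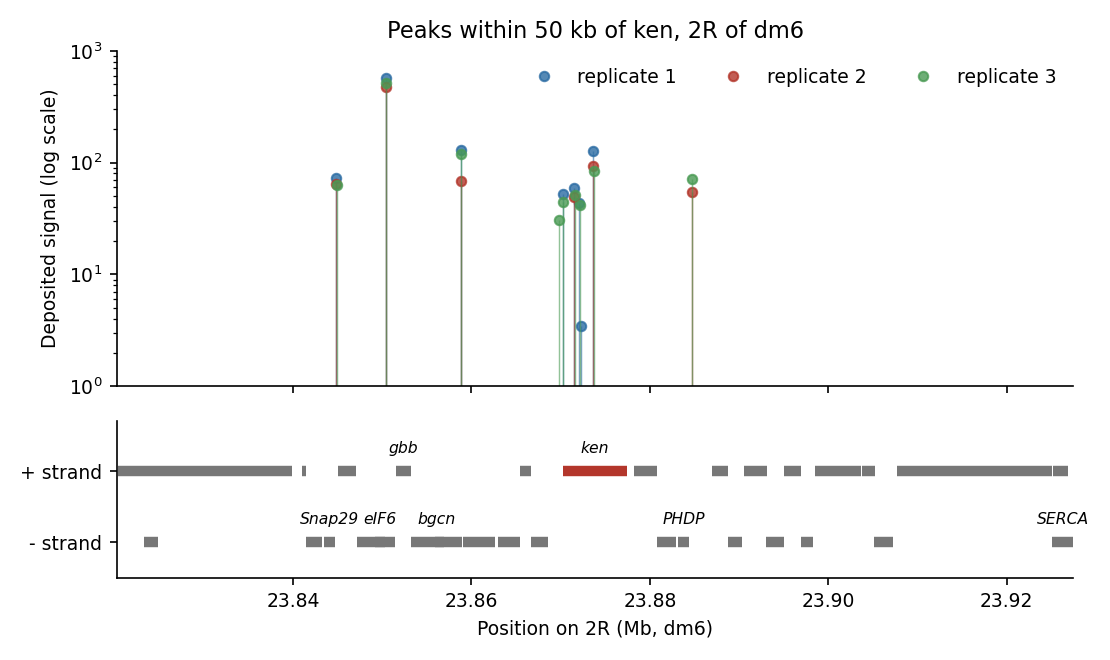
Deposited signal (log scale) of the thresholded peaks of each replicate within 50 kb of ken on 2R (dm6), each drawn at its summit, above the protein-coding genes of both strands, with ken in red. All 3 replicates have peaks at 5 shared places, of which the highest, near eIF6, has signals of 572.8, 470.8 and 520.1.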

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

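Over 110 recalculated values, 92 kept their direction and side of the threshold or moved little, 10 lost the threshold, 1 turned its direction and 7 counts or values moved. Not all of the 92 could have come out otherwise. Overlaps with a replicate left out reuse the main pairwise values and were counted as unchanged. Of the single gene lists, only the 4 that had passed entered the tally. A list that newly passed, such as the ecdysone list, could therefore not be counted as a gain. IDRs of 0.05 and 0.001, and leaving out replicates for peak numbers and at ken, were chosen after seeing the data. The mean number of peaks per replicate was 1209.3 with the stronger 50% of each list, 3644.7 at an IDR of 0.05 and 1516.0 at 0.001, by construction, and 2056.0 to 2700.0 with a replicate left out. The core sites numbered 774 with the stronger 50% and 2131 with at least 2 of 3 replicates, by construction, and 1476 to 1826 when a replicate was left out. Signal correlations ranged from 0.815 to 0.826 with a replicate left out. The Ken motif stood 1.806 percentage points above shuffled sequence and below flanks in each other setting; the cause was not tested. With the stronger 50%, 2 gene lists passed in place of 4, with fewer sites tested. The window at ken held 5 to 7 sites without 1 replicate; without replicate 3, with 5 sites, the share of windows with as many was 0.07. An IDR of 0.01 changed nothing, because the deposited lists end there. Read depth is unknown, so its limit on replicate 2, with the shortest list, could not be computed. No paired analysis was possible because there is 1 group.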

Other observations

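Tests on mitochondrial ribosomal proteins and on 7-mers, the pooling over pairs, the ranks and the IDR of 0.05 for peaks of 1 replicate, and the bootstrap interval for ribosomal sites were chosen after related values had been seen. Not all genes of basic cell functions were bound like the cytoplasmic ribosome. Of 48 proteasome subunit genes, 0% had a core site within 1 kb of a TSS, against 9.20% of other genes (two-sided Fisher's exact p = 0.0203, not adjusted). Mitochondrial ribosomal protein genes, which supply mRpL41 and mRpL23 among the strongest sites, were bound in 13.7% of 73 cases against 9.14% of other genes (Fisher's exact p = 0.217). The proteasome result goes against a preference for all housekeeping genes, but it rests on an unadjusted test of the core sites only. Whether each of the 48 genes is active in embryos was not tested.

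Core sites were frequent where genes on opposite strands start close together. Whether such genes point away from each other, and whether the site lies between their starts, was not tested. Of the 755 promoter core sites, 41.5% had TSSs of different genes on opposite strands within 500 bp, against 27.2% on average for random TSSs taken at the same offsets and 32.6% in the highest of 1000 draws (one-sided permutation p = 0.001, the smallest possible). A hypothesis is that the protein prefers shared promoters, and the test came out in its favour, although it does not separate gene arrangement from the openness of such promoters.

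The Ken motif did not mark the strongest sites. It was found in 9.54% of the stronger 50% of core sites and 13.4% of the weaker 50%, the opposite of what that hypothesis predicted (two-sided Fisher's exact p = 0.0282, not adjusted). This test did not use flanks, so it does not show a lack of the motif at strong sites relative to nearby sequence. With the stronger 50% of each list, the difference from flanks was -1.94 percentage points (exact sign test p = 0.261). Base content was to be tested with the reversed motif, which had a centre over flank ratio of 1.02 where GNGAAAK had 0.869. That test was void, because GNGAAAK itself was not in excess.

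Other short sequences may mark part of the sites. Of 6705 7-mers, 2 were picked on X, 2L and 2R for an excess over both flanks and shuffled sequence, AAAATAT and ATATTTC, and 2 of 2 kept it on 3L and 3R. Neither holds the CGATA or GGCGC of insulator elements, so this search did not decide between such elements and others. A look at 8-mers over all core sites then gave TATCGATA, AGATGGCG, CAACACTG and CCACTGTG, and these were tested at the 735 sites called in exactly 2 replicates, which had not been searched for the last 3; TATCGATA, the planned DREF motif, had already been seen in excess in the full lists that hold these sites. There 3 of the 4 were in excess over flanks by exact sign tests: TATCGATA at 27 sites against 4 flanks (adjusted p = 0.000136), CAACACTG at 23 against 3 (adjusted p = 0.000176) and CCACTGTG at 16 against 4 (adjusted p = 0.0158). AGATGGCG, which resembles the core of the CTCF site, was found at 13 against 6 (adjusted p = 0.167, exact sign test). Any of the 4 was present at 10.3% of those sites, 4.34% of the stronger 50% of core sites and 8.82% of the weaker 50%, so most sites had none of them.

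Peaks called in 1 replicate only mostly had a ranked peak in the other replicates. Pooled over the 6 directed pairs, 83.2% overlapped another replicate's ranked list (77.7% to 92.2% by pair, 34.6% in the highest of the shifted lists), above the 80% written down beforehand for sites just under the threshold. Their partners had median ranks of 4974 to 6457 by pair, in ranked lists of 101546 to 123371 peaks of which 1856 to 3144 were in the thresholded lists. At an IDR of 0.05, 17.5% had a partner (exact 95% interval 16.1 to 18.9), and 30.5% of the 1487 peaks had one in at least 1 other replicate. The pooled share counts each peak once for each other replicate, so its interval is likely too narrow. How far below the threshold still counts as just under was not written down beforehand, so whether such sites are the source of most of these peaks stays open. Whether they are places that Ken occupies rarely stays open, because the motif meant to tell was not in excess at core sites (-1.73 percentage points) or at these peaks (-1.88, exact sign test p = 0.152).

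The core sites in and around ken may reflect extra copies of the region on the transgene. If the whole region were raised, the ranked lists would hold more or higher peaks there than in 95% of random gene windows. The number of ranked peaks lay at percentiles from 73.5 to 82.7 in the 3 replicates and their median signal at 83.5 to 91.0, below the 95% predicted for a rise of the whole region. A rise over only part of the window was not tested, so the values do not exclude extra copies. All of these lie above the middle of the random windows, so a small rise stays open, as does binding of Ken at its own gene, which was not tested.

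Sites at ribosomal protein genes raise the question of unspecific recovery of heavily transcribed chromatin. Of 290 tRNA genes, which another polymerase transcribes heavily, 3.45% lay within 1 kb of a core site. Shifted sites gave 2.02% (one-sided permutation p = 0.143), and 39.8% of the ribosomal protein genes were bound. The tRNA share was above that of shifted sites, but not detectably so. A modest excess at genes of that other polymerase is therefore not excluded. The comparison does not reach genes of RNA polymerase II, so it cannot exclude recovery by transcription there. The 39 ribosomal sites were not the strongest, with a median mean rank of 731.3 (bootstrap 95% interval 617.7 to 963) against 705.7 for other promoter sites (permutation p = 0.868) and a bound of 383.2 for the strongest 25%. Of the 39 sites, 5 had another gene's TSS as the nearest. The sites were chosen for lying within 1 kb of a ribosomal protein gene TSS, so this does not show which gene a site belongs to. A neighbouring gene or a shared promoter stays open: 70.3% of bound and 58.9% of unbound ribosomal protein genes had another gene's TSS within 1 kb (Fisher's exact p = 0.282). A GFP sample without Ken was not analysed here, so unspecific recovery at promoters of RNA polymerase II stays open as well.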
